A study of Homo sapiens with 24 samples.

How the data were processed

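Gene expression was measured in 24 skin biopsies on single-colour 44K oligonucleotide arrays, 1 array per biopsy. The titles of the samples pair 4 biopsies with each of 6 volunteers, 1 each of unexposed control skin and of skin exposed to SSR, UVA or UVB. Per the labels' protocols, RNA was isolated with Trizol and labelled with Cy3 after linear amplification. The deposited files hold the spot intensity read by Agilent Feature Extraction 9.5.1.1, per the file headers, and are not normalized between arrays. Per the file headers, the processed signal is the spot intensity after background subtraction and spatial detrending, with low values replaced by surrogates. The mean signal of a spot and its local background, also deposited, were used only in an alternative. Each array holds 45015 spots, of which 43376 are not controls, and these carry 41000 different probes. No genome build is given in the sources used here, so no coordinates are printed.

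The processed signal was taken to log2 and each array's 75th percentile of it was subtracted. Control spots and spots marked as outliers were left out, spots of 1 probe were averaged, and 104 probes for Y-linked genes, XIST and TSIX were removed from every step. A probe was tested if it was well above background on at least 6 of the 24 arrays, and a gene was represented by its probe with the highest mean, which left 25173 genes. Where a gene named in the report had several probes that moved in opposite directions, or apart by more than 1.5-fold, this is stated beside it, except where only a bound or no fold is given. Gene names came from the RefSeq accession of a probe for 23845 probes, from a current symbol for 2018 and from an older symbol for 966, and the name in the file was kept for 14171, so that 15501 of the genes tested carry a current symbol. Where no array of a group measured a probe well above background, only a bound is given, written "at least N-fold", which is the brighter group's mean against the higher of the dim probe's own signal and the lowest signal well above background on each array. Where only some arrays of a group did, their number is given in the report, as is that of arrays with a saturated spot, where a fold is not exact.

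Tests were made with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table, as 1 fit over all 24 arrays with a mean-variance trend, moderated statistics and Benjamini-Hochberg adjustment over genes at 0.05, two-sided. The unpaired comparison, which was set as the first test before the data were examined, has the group as its only term. The paired comparison, planned at the same time as its alternative, adds the volunteer as a block. Arrays of the same volunteer deviated together from their group means over all genes, with a median correlation of 0.63 (from 0.259 to 0.827 over 36 pairs) against -0.154 for 180 pairs of other volunteers and groups. For 24 of 24 arrays, the best correlated array of another group came from the same volunteer. The titles therefore pair the arrays, and because the block changed nearly every count, both comparisons are printed. The mean changes of lists differ slightly between them, by 0.01 log2 or less, because spots left out weigh differently, and those of the paired comparison are printed unless the unpaired one is named. The words rose, fell and called stand for an adjusted p under 0.05 in the paired comparison unless the unpaired one is named, and errors are the SD of the 6 changes within volunteers. No 2 arrays of a group were alike enough to be 1 hybridisation deposited again: the SD of their log2 difference was 0.541 or more over all 60 pairs.

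The genes named in the text follow a rule set before the data were examined. For each comparison with control it takes the 8 risen and 8 fallen genes with a current symbol and the largest mean change among those called and changed alike in at least 5 of 6 volunteers, or, with none called, the 5 with the smallest p. For comparisons between exposures it takes 5 and 5. It adds up to 3 members of each gene list, and 28 genes named whatever their values. The rule was applied to the unpaired comparison and, as decided after the effect of pairing was seen, to the paired comparison as well. Other members of the lists, named as examples, were chosen after their values were seen. The text gives the values of the genes always named and of a part of the others that the rule takes, and 3 genes are left out of the named genes and not reported here.

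There were 30 gene lists, also set before the data were examined. They hold melanocyte pigmentation genes, paracrine pigmentation factors, p53 target genes, nucleotide excision repair, late epidermal differentiation, stress keratins and epidermal alarmins, basal keratinocytes and basement membrane, cell cycle, dermal extracellular matrix, matrix proteases and their inhibitors, NRF2 and oxidative stress targets, metallothioneins, interferon response, inflammatory cytokines and chemokines, vitamin D metabolism, cholesterol synthesis, epidermal ceramide barrier and circadian clock. The other lists mark cell types or structures, namely Langerhans and dendritic cells, T and NK cells, macrophages, neutrophils, mast cells, endothelium, adipocytes, sweat gland, sebaceous gland and hair follicle, muscle, Schwann cells and nerve, and blood cell haemoglobin. Each list was tested against all other genes with camera of limma at a preset correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated from the data. With an estimated correlation, 3 lists were called in the paired comparison of SSR with control and 0 in every other comparison, paired or unpaired, where the preset correlation called from 2 to 11.

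The scripts were tested on simulated data with 50 genes changed by each of 4 fold sizes among 25173 genes. For SSR against control the paired comparison recovered 14 genes at 1.5-fold, 38 at 2-fold, 49 at 3-fold and 47 at 4-fold with 3 calls among unchanged genes, and the unpaired comparison recovered 1, 18, 31 and 37 with 0. For UVA the paired numbers were 17, 45, 46 and 49 with 0 false calls and the unpaired ones 0, 15, 35 and 42 with 0. For UVB they were 19, 46, 50 and 48 with 47 false calls, and 4, 17, 41 and 42 with 0. A simulated list raised 2-fold was called in SSR against control, with an estimated mean of 0.846 log2. At the preset correlation, however, 5 of 29 unchanged lists were called too in the paired comparison and 3 of 29 in the unpaired one. A list call at the preset correlation alone is therefore weak evidence.

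The arrays lie on 6 slides of 4. Slide 1 holds 4 control arrays, slide 2 holds 2 control and 2 SSR, slide 3 holds 4 SSR, slide 4 holds 4 UVA, slide 5 holds 2 UVA and 2 UVB, and slide 6 holds 4 UVB. Only SSR against control and UVB against UVA can be compared within a slide. Alternatives tried were the pairing with and without quantile normalization, normexp background correction with an offset of 50, quantile and median scaling, no filter or a filter on all 24 arrays, no mean-variance trend, array weights, the mean of all probes of a gene, a 1.5-fold minimum, only the arrays compared, slide as a random or fixed block, estimated correlations in the list tests, and leaving out each array and each volunteer. Added after seeing the data were the same alternatives for the paired comparison, the fixed slide block there, the fits without the 4 UVB arrays of slide 6, and overlaps from separate volunteers. The number of arrays limits the precision of every value. Volunteers are not numbered in the text.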

Results

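The data are gene expression profiles of skin biopsies from 6 volunteers, 4 from each. Of every 4 biopsies, 1 was of unexposed control skin and the others of skin exposed to SSR, UVA or UVB, which gives 4 groups of 6 arrays. UVA and UVB are the long-wave and short-wave parts of the ultraviolet light that reaches skin. The labels do not expand SSR, which in photobiology commonly stands for solar-simulated radiation, a lamp spectrum that holds both. There were 10 exposures, 5 per week for 2 weeks, and the skin was sampled 3 days later. The series asks how repeated exposure regulates pigmentation in skin and how the responses to the 3 kinds of radiation differ. The labels used here give no doses.

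The share of probes well above background was 79.5% ± 2.71 (SD, n = 6) on control arrays, 80.8% ± 2.19 on SSR arrays, 77.7% ± 2.85 on UVA arrays and 73.8% ± 4.28 on UVB arrays. The 4 UVB arrays of slide 6 had the lowest shares of all, from 68.9% to 72.7%, and are called the dim slide here. The 75th percentile of the processed intensity ran from 601 on a UVB array to 2174 on a control array before scaling.

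**Figure D1:**
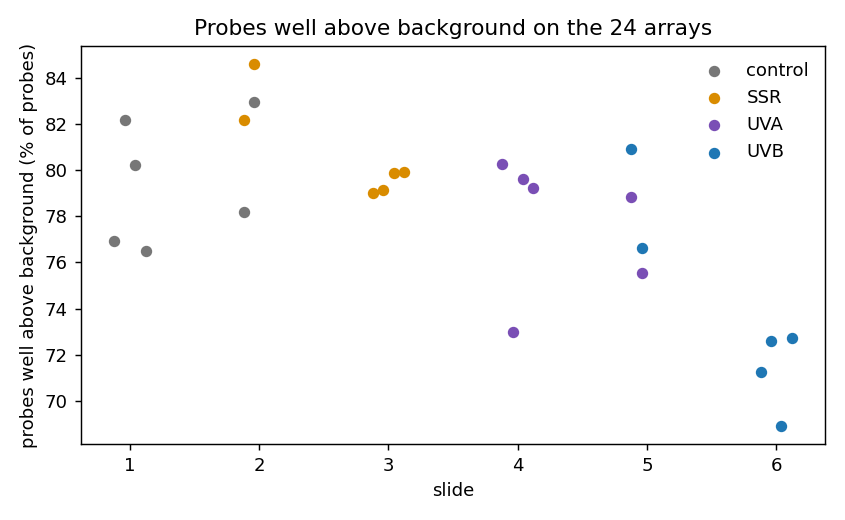
Each point is 1 of the 24 arrays, placed by its slide (x axis) and its share of probes well above background in percent (y axis), and coloured by group. The 4 arrays on slide 6, all UVB, lie between 68.9% and 72.7%, below the other 20.

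After SSR, genes of melanocytes, the pigment cells of the epidermis, were higher than in the volunteer's own control skin in 6 of 6 volunteers, and genes of Langerhans and dendritic cells, which present antigen, were lower in 6 of 6. Of the 21 melanocyte pigmentation genes measured, 17 rose and 1 fell, and their mean change was 1.42 ± 0.531 log2 (SD, n = 6), or 2.67-fold. TYRP1, TYR and DCT, enzymes of melanin synthesis, were 6.46-fold, 4.55-fold and 3.59-fold higher. PMEL, which forms the fibrils of the melanosome, was 5.86-fold higher. Of the 16 Langerhans and dendritic cell markers, 12 fell and 0 rose, with a mean change of -0.71 ± 0.394.

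Among other melanocyte genes, the lineage factors MITF, SOX10 and PAX3 rose 1.95-fold, 2.92-fold and 4.53-fold, PAX3 being well above background on 5 of 6 control arrays. Weaker probes of MITF and PAX3 rose by 0.29 and 1.06 log2. MLANA rose 4.51-fold and KIT, the receptor for stem cell factor, 3.88-fold. The member that fell was BCL2A1, an inhibitor of cell death that blood cells also express, by 0.50 log2. CD207, the langerin of Langerhans cells, fell 1.79-fold and CD1A, which presents lipids, 1.67-fold. The class II antigen-presenting chains HLA-DRA and HLA-DQA1 fell 1.95-fold and 1.92-fold, and CD1C fell 2.05-fold.

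Among called genes with a current symbol, the largest rise after SSR was of CCL18, a chemokine of macrophages and dendritic cells, at 8.02-fold (log2 3.00 ± 1.03, adjusted p = 6.02e-06 paired and 0.692 unpaired, well above background on 5 of 6 control arrays). SLC6A15, an amino acid transporter (5.77-fold, with another probe at 0.86 log2, 3 of 6 control arrays well above background), and TRIM63, a ubiquitin ligase (4.91-fold), were also among the 8 largest rises, with TYRP1, PMEL, TYR, PAX3 and MLANA. The largest falls were of NTM (log2 -2.45 ± 0.953, 2 of 6 SSR and 5 of 6 control arrays well above background), the cytokine IL13 (-2.10 ± 0.753, 2 of 6 SSR arrays) and SLIT2, a guidance factor (-2.01 ± 0.594, 5 of 6 SSR arrays). PTPRD, ABI3BP and SUCNR1 fell by 1.72, 1.66 and 1.57 log2, with 3, 4 and 4 of 6 SSR arrays well above background. SPP1, the secreted protein osteopontin, fell 3.09-fold, and SUPT3H, well above background on 5 of 6 control arrays and 0 of 6 SSR arrays, fell at least 1.65-fold.

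Of 24 inflammatory cytokines and chemokines measured after SSR, 2 rose, CCL18 and CCL3, and 8 fell, among them CXCL1 (2.24-fold), CCL20 (1.92-fold), and IL1B and CXCL8, which fell by 0.88 and 1.09 log2. Over the list alone, 3 rose and 9 fell. Of 19 T and NK cell markers 3 fell, GZMB (1.87-fold), CD8A (1.83-fold) and CD247 (2.67-fold, 3 of 6 SSR and 4 of 6 control arrays well above background), and 4 when adjusted over the list alone. Of 23 dermal extracellular matrix genes, FN1 (2.39-fold), FBN1 (2.27-fold) and SPARC (1.96-fold) rose and DCN fell by 0.41 log2. Beside them, the mean of adipocyte markers was 0.35 ± 0.291, above 0 in 6 of 6 volunteers, and that of Schwann cell markers 0.43 ± 0.352 in 5 of 6, neither list being called. Among other genes, CYP24A1, which breaks down vitamin D, rose 1.51-fold, CYP27A1 of the same pathway 2.25-fold (5 of 6 control arrays well above background) and the protease inhibitor TIMP2 1.72-fold. MMP9 and MMP12, matrix-degrading proteases, fell 1.65-fold and 1.95-fold. PTGS2, CSF2 and IL1A, which can act on melanocytes as paracrine signals, fell 1.83-fold, 2.27-fold (5 of 6 SSR arrays well above background) and 1.91-fold. KITLG (0.27 ± 0.397), EDN1 (-0.21 ± 0.341) and POMC (0.07 ± 0.371) did not pass, nor did the p53 targets CDKN1A (0.17 ± 0.217) and MDM2 (0.35 ± 0.445). Of the keratins, KRT5 (0.22 ± 0.177), KRT14 (0.26 ± 0.241), KRT10 (0.23 ± 0.132) and KRT1 (0.11 ± 0.149, saturated on 3 of 6 control arrays) did not pass. Other genes of differentiation and stress, FLG (-0.31 ± 0.73), LORICRIN (-0.02 ± 0.431), IVL (0.48 ± 0.524), SERPINB2 (-0.35 ± 0.255) and HMOX1 (-0.28 ± 0.368), did not pass either, nor did COL1A1 (0.03 ± 0.27), ELN (0.32 ± 0.363) and MMP1 (-0.04 ± 0.212, with its other probe at 0.75). COL3A1 (3 of 6 SSR and 4 of 6 control arrays well above background) and the proliferation marker MKI67 (2 and 1 of 6) changed by 0.08 ± 1.85 and 0.06 ± 1.92.

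Over all 25173 genes, 395 rose and 335 fell after SSR in the paired comparison, 54.1% upward against 39.2% of 204 calls with normexp background correction. In the unpaired comparison limma called 0, with 1007 at an unadjusted p under 0.05. PMEL had an adjusted p of 1.02e-05 paired and 0.235 unpaired, and TYRP1 9.86e-06 and 0.559. The melanocyte list had an adjusted p of 4e-28 paired and 9.07e-20 unpaired, and the Langerhans and dendritic cell list 1.24e-21 and 6.87e-17. Both had an adjusted p = 0.0135 with an estimated correlation when paired, and 0.112 and 0.0531 when unpaired. Adjusted over the list alone, 17 melanocyte genes rose and 1 fell when paired, and 17 and 0 when unpaired. The inflammatory list (mean -0.26 ± 0.198) had an adjusted p of 4.11e-05, and 0.028 with an estimated correlation when paired but 0.259 when unpaired. The lists of T and NK cell markers (mean -0.42 ± 0.321), cell cycle genes (mean -0.16 ± 0.301, 0 of 35 called) and dermal extracellular matrix (mean 0.34 ± 0.168) were called only at the preset correlation, with an adjusted p = 0.62, 0.62 and 0.229 with an estimated correlation. The list of NRF2 and oxidative stress targets (mean -0.06 ± 0.199) was called only when unpaired (adjusted p of 0.0401 against 0.107 paired), with an adjusted p = 0.259 with an estimated correlation. Of the 57 named genes called, 31 lost their call with normexp and 20 without at least 1 of the volunteers, when from 382 to 580 genes were called. With slide as a fixed block 0 single genes were called when paired, while the melanocyte mean was 1.28 log2 and the Langerhans and dendritic cell mean -0.99. Within the slide that holds 2 control and 2 SSR arrays, unpaired, these means were 2.68 and -0.58, and the cell cycle and inflammatory means turned to 0.25 and 0.19. The unpaired values of that slide were not matched by volunteer and also hold differences between persons.

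**Figure D2:**
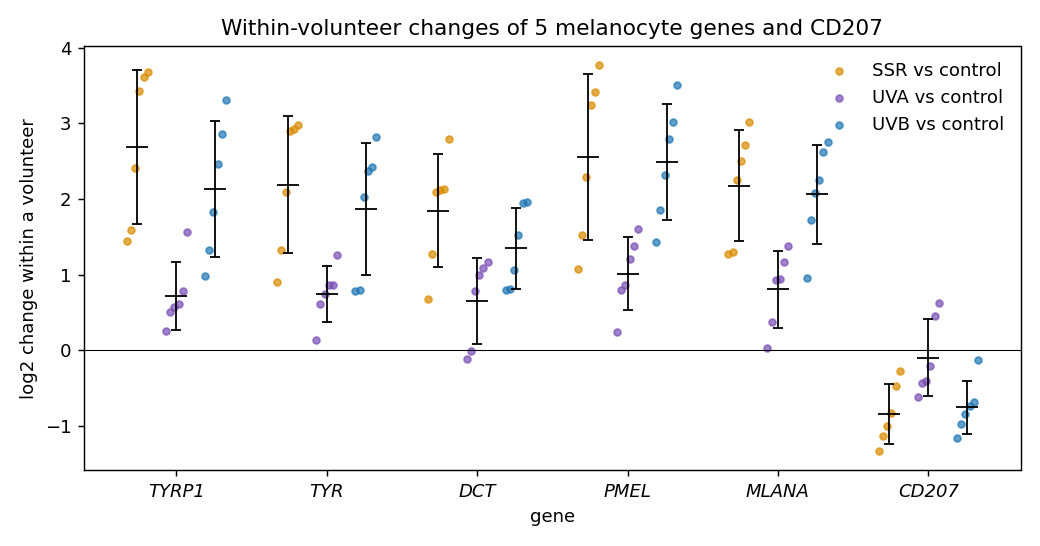
Points are log2 changes within each of 6 volunteers (y axis) after SSR, UVA or UVB for 5 melanocyte genes and CD207 (x axis), with the mean and SD as bars. All 5 melanocyte genes lie above 0 in 6 of 6 volunteers after SSR and UVB, and DCT in 4 of 6 after UVA, where its mean was 0.65 ± 0.571.

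After UVA, changes of the same genes were smaller. The mean change of the 21 melanocyte genes was 0.50 ± 0.298 log2 (SD, n = 6), above 0 in 6 of 6 volunteers. Only PMEL (2.02-fold) and MLANA (1.75-fold) rose over all genes tested, while 13 members rose when adjusted over the list alone. TYR, TYRP1 and DCT changed by 0.75 ± 0.371, 0.72 ± 0.448 and 0.65 ± 0.571 and did not pass. The mean of the 16 Langerhans and dendritic cell markers changed by -0.08 ± 0.326, and 0 of them passed.

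Among called genes with a current symbol, the largest rises after UVA were of GCNT3, a glycosyltransferase of mucin synthesis (log2 2.96 ± 1.12, 2 of 6 control arrays well above background), ZG16 (2.71 ± 1.08, 4 of 6 control arrays) and SLC14A1, a urea transporter (2.43 ± 1.15). FOXR1, MFAP5 and BMP3 rose by 2.41, 2.38 and 2.25 log2, with 4 and 3 of 6 control arrays well above background for MFAP5 and BMP3. OR4C46, an olfactory receptor gene, rose 5.15-fold, with 5 of 6 control arrays well above background. The largest falls were of SPTSSB, a subunit of sphingolipid synthesis (log2 -1.44 ± 1.34), the signal protein WNT5A (-0.89 ± 0.432, 4 of 6 UVA arrays well above background), FBXO36 (-0.87 ± 0.439) and the transporter ABCC4 (-0.86 ± 0.465, with its other probe at -0.04). C1QL1, CITED2, NFE2L3 and the iron exporter SLC40A1 fell 1.74-fold, 1.73-fold, 1.72-fold and 1.65-fold.

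The keratins KRT5 and KRT14 of basal cells rose 1.37-fold and 1.41-fold after UVA, and KRT1 of differentiating cells 1.43-fold, a fold that is not exact since KRT1 was saturated on 5 of 6 UVA and 3 of 6 control arrays. The ribosomal protein genes RPL27A, RPS10 and RPS28, which with LONRF3 (2.24-fold) were among those with the smallest p in the unpaired comparison, were 1.40-fold, 1.42-fold and 1.39-fold higher, RPS28 with 1 of 6 UVA and 2 of 6 control arrays saturated. These 3 keratins and 3 ribosomal genes kept their direction under quantile normalization and lost their calls there. Of the 35 named genes called after UVA, 25 lost their call in that setting. AKR1C1 and AKR1C3, reductases induced by oxidative stress, rose 1.60-fold and 1.52-fold, while TXNRD1 of the same list fell 1.47-fold. CYP24A1 rose 1.48-fold, the protease MMP3 1.67-fold and RPA3, a DNA repair subunit, 1.57-fold. The heme oxygenase HMOX1 (-0.28 ± 0.469), CDKN1A (0.03 ± 0.243, with its other probe at -0.52), MKI67 (0.71 ± 0.908, 2 of 6 UVA and 1 of 6 control arrays well above background) and COL1A1 (0.30 ± 0.273) did not pass. CD207 (-0.10 ± 0.511), CD1A (-0.12 ± 0.285), KITLG (0.17 ± 0.41), EDN1 (0.09 ± 0.86), POMC (-0.03 ± 0.353), KRT10 (0.37 ± 0.25), LORICRIN (-0.96 ± 1.78), IVL (0.02 ± 0.476) and SERPINB2 (-0.18 ± 0.135) did not pass either. MITF (0.59 ± 0.733, probes from -0.15 to 0.59), MDM2 (0.35 ± 0.537, from -0.08 to 0.35), FLG (-0.55 ± 0.743, from -0.55 to 0.12), ELN (0.30 ± 0.271, from -0.18 to 0.30) and MMP1 (0.21 ± 0.203, from -0.21 to 0.21) did not pass and had probes in opposite directions. COL3A1 changed by -0.33 ± 2.25, with 2 of 6 UVA and 4 of 6 control arrays well above background.

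In the paired comparison 568 genes rose and 69 fell after UVA, 89.2% upward against 83.2% of 184 calls under quantile normalization and 74.5% of 239 with normexp background correction. In the unpaired comparison limma called 0, with 1042 at an unadjusted p under 0.05. At the preset correlation 9 lists were called when paired, and 0 with an estimated correlation. With an adjusted p = 0.611 with an estimated correlation each, these were the melanocyte list (adjusted p of 1.23e-05 paired and 0.00852 unpaired), the epidermal ceramide barrier (mean -0.38 ± 0.479, 1 of 16 fell, FA2H), metallothioneins (0.27 ± 0.137, higher in 6 of 6 volunteers, 0 of 10 called over all genes and 5 rose over the list alone), neutrophil markers (-0.56 ± 0.812, 0 of 11 called over all genes) and basal keratinocytes (0.21 ± 0.197, 3 of 15 rose). Cholesterol synthesis (-0.22 ± 0.308) and p53 targets (-0.11 ± 0.108) had an adjusted p = 0.74 with an estimated correlation, and cell cycle (0.19 ± 0.3, 1 of 35 rose, UBE2C) and late epidermal differentiation (-0.28 ± 0.576, 1 of 27 rose, KRT1) an adjusted p = 0.768 with an estimated correlation. Unpaired, the calls for basal keratinocytes and cell cycle were lost (adjusted p of 0.0589 and 0.0919). With normexp, which moved the median of all genes to 0.376, the melanocyte mean was 0.47, and metallothioneins at 0.12 and basal keratinocytes at 0.04 lay below that median. The neutrophil mean, WNT5A, FBXO36, ABCC4 and SLC40A1 turned to values above 0 there, but FBXO36 and SLC40A1 stayed below that median. No UVA array shares a slide with a control array, and leaving out 1 of the 6 volunteers at a time gave from 17 to 538 paired calls, with 33 of the 35 named genes called here losing their call in at least 1 such fit.

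After UVB, most melanocyte genes rose and most Langerhans and dendritic cell genes fell, while both lists had an adjusted p = 0.472 with an estimated correlation, against 0.0135 after SSR. Of 21 melanocyte genes 17 rose and 1 fell, BCL2A1, with a mean change of 1.23 ± 0.415 log2 (SD, n = 6) and 6 of 6 volunteers above 0. PMEL, TYRP1, MLANA and TYR were 5.59-fold, 4.37-fold, 4.18-fold and 3.65-fold higher, DCT 2.54-fold and MITF 2.05-fold. Of 16 Langerhans and dendritic cell markers 12 fell, with a mean of -0.62 ± 0.267, among them CD1C (2.09-fold), HLA-DQA1 (1.88-fold, with another of its 4 probes at 0.09), CD1A (1.72-fold) and CD207 (1.68-fold). CCL18 rose 6.12-fold, with 5 of 6 UVB and 5 of 6 control arrays well above background.

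Other large rises after UVB were of GFRA4, a growth factor receptor (log2 2.96 ± 1.51, adjusted p = 8.77e-05 paired and 0.0422 unpaired), ZG16 (2.92 ± 1.93), FOXR1 (2.72 ± 2.01), OR4C46 (2.68 ± 1.98), SLC14A1 (2.61 ± 1.96) and GCNT3 (2.53 ± 1.89), the last 5 of them also among the largest rises after UVA. Of these 5, ZG16, OR4C46 and GCNT3 were well above background on 4, 5 and 2 of 6 control arrays, and GCNT3 on 5 of 6 UVB arrays. In the unpaired comparison SMIM43, POMK, MAGEA6, LPAL2 and GPR78 were among the 8 largest rises, from 3.48-fold for GPR78 to 4.94-fold for SMIM43. LPAL2 was well above background on 2 of 6 UVB and 1 of 6 control arrays, SMIM43 on 5 and 3, and POMK on 5 and 4. The largest falls were of NTM (log2 -2.19 ± 0.932, 1 of 6 UVB and 5 of 6 control arrays well above background), SLIT2 (-1.90 ± 0.707, 1 of 6), GPR85 (-1.78 ± 0.973, with its other probe at -1.11, 3 of 6) and SPP1 (-1.69 ± 0.808, 4 of 6). Not well above background on any UVB array, ZRANB3 fell at least 1.49-fold, SLN at least 1.38-fold and FCGR3B at least 1.19-fold, while SUPT3H and MCMDC2 were called lower with no fold to be given. Of these 5, FCGR3B and SUPT3H were well above background on 4 and 5 of 6 control arrays. CLEC5A, TNFAIP8L2, MACROD2 and SLA, the first of them a receptor of myeloid cells, fell 2.62-fold, 2.27-fold, 2.12-fold and 2.01-fold and were called in the unpaired comparison as well. For SLA a second probe changed by 0.08, and for MACROD2 the 3 probes ran from -1.74 to -0.52.

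Of 23 dermal extracellular matrix genes 12 rose after UVB, among them SPARC (1.79-fold), ELN, the elastic fibre protein (1.59-fold), COL1A1 (1.45-fold) and MFAP5 (5.17-fold, 4 of 6 control arrays well above background), and 2 fell, DCN and POSTN, by 0.43 and 0.91 log2. Beside them, the markers of adipocytes (mean 0.49 ± 0.278) and sweat glands (0.18 ± 0.143) were higher in 6 of 6 volunteers and those of Schwann cells (0.40 ± 0.302) and endothelium (0.28 ± 0.4) in 5 of 6, none of these lists being called. Of 10 metallothioneins, which bind zinc and copper, 7 rose, including MT1A (1.35-fold) and MT1X (1.28-fold), and 8 when adjusted over the list alone. ASIP, an antagonist of the melanocortin receptor, rose 2.10-fold and was called in the unpaired comparison as well (adjusted p = 0.000305 paired and 0.0456 unpaired), and HGF, a growth factor for melanocytes, rose 1.77-fold. Of 24 cytokines and chemokines 2 rose and 6 fell, among them CXCL8 (2.28-fold) and IL1B (1.93-fold). The list's mean of -0.13 ± 0.0811 turned to 0.16 with normexp, still below the median of all genes there, 0.385. Of 28 p53 targets 7 rose and 3 fell, with BBC3 1.69-fold (another probe at 0.14 log2) and DDB2 1.32-fold higher and FAS 1.41-fold lower, while CDKN1A (0.25 ± 0.228, with its other probe at -0.18) and MDM2 (0.08 ± 1.04) did not pass. Over all 25173 genes 5280 rose and 2077 fell after UVB, so the counts of p53 targets lie near the shares of all genes. KRT5 and KRT14 were 1.49-fold higher each and KRT1 1.60-fold, which is not exact since it was saturated on 1 of 6 UVB and 3 of 6 control arrays, but under quantile normalization KRT5 and KRT1 lost their calls and KRT10, 1.25-fold higher here, turned to -0.09. SERPINB2 and TXNRD1 fell 1.55-fold and 1.84-fold. KITLG (-0.01 ± 0.316, with other probes from -0.35 to 0.21), EDN1 (0.11 ± 0.839), POMC (0.08 ± 0.165), FLG (-0.72 ± 0.69), LORICRIN (-0.40 ± 1.34), IVL (-0.06 ± 0.544) and HMOX1 (-0.52 ± 0.52) did not pass, nor did MMP1 (-0.13 ± 0.508, with its other probe at 1.52). COL3A1 (1 of 6 UVB and 4 of 6 control arrays well above background) and MKI67 (2 and 1 of 6) changed by -0.18 ± 1.65 and 1.05 ± 1.15.

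In the paired comparison 5280 genes rose and 2077 fell after UVB, 71.8% of calls upward, against 55.9% of 7002 calls under quantile normalization. In the unpaired comparison 245 rose and 19 fell, 92.8% upward, against 65.3% of 98 calls under quantile normalization. The melanocyte and the Langerhans and dendritic cell lists had adjusted p of 2.57e-09 each when paired, and 1.77e-05 and 3.48e-06 when unpaired, with adjusted p = 0.472 each with an estimated correlation when paired and 0.737 and 0.394 when unpaired. Metallothioneins (mean 0.33 ± 0.255) had an adjusted p of 0.0175, and 0.755 with an estimated correlation. When unpaired, dermal extracellular matrix (mean 0.44 ± 0.157), cholesterol synthesis (-0.19 ± 0.337), the ceramide barrier (-0.21 ± 0.375) and NRF2 targets (-0.16 ± 0.158) were also called, with an adjusted p = 0.394 or more with an estimated correlation, and when paired their adjusted p was 0.0533, 0.0533, 0.072 and 0.0617. Without the 4 arrays of the dim slide, a setting chosen after seeing the data, the paired comparison called 4194 genes and the unpaired one 0, and the melanocyte and Langerhans and dendritic cell means were 1.33 and -0.57. With normexp, which moved the median of all genes to 0.385, the metallothionein mean of 0.21 lay below that median. The falls of NTM, SLIT2, GPR85, ZRANB3, SLN, FCGR3B, SUPT3H and MCMDC2 turned to values above 0, but SLIT2 stayed below that median. Of the 114 named genes called, 68 lost their call. Leaving out 1 array at a time moved the unpaired count between 8 and 1478, leaving out 1 volunteer the paired one between 4768 and 6493, and no UVB array shares a slide with a control array.

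**Figure D3:**
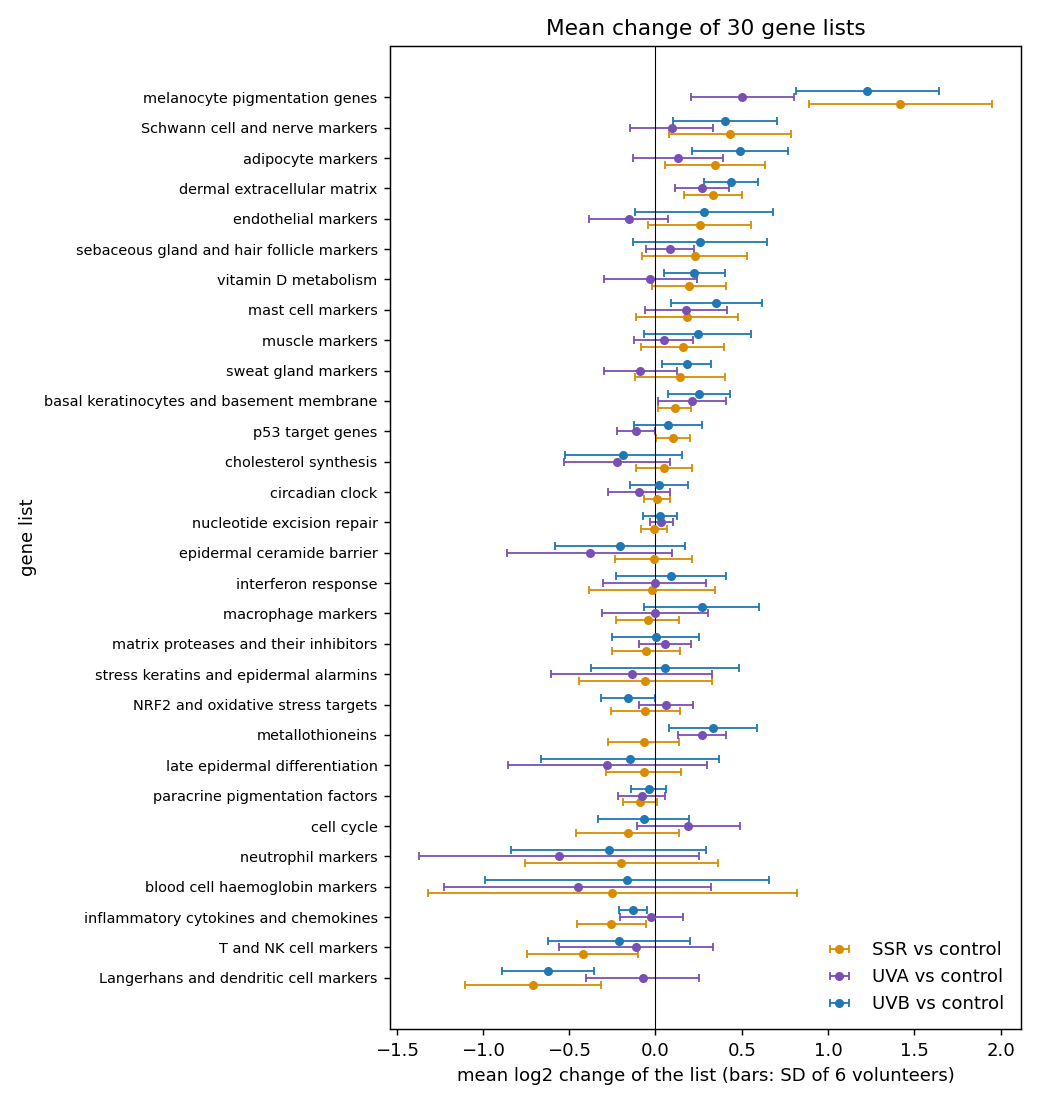
Mean log2 change of each of 30 gene lists (y axis) after SSR, UVA and UVB (x axis), with points as the mean of 6 volunteers and bars as the SD of their means. Melanocyte pigmentation genes lie highest, at 1.42 for SSR, 1.23 for UVB and 0.50 for UVA, and Langerhans and dendritic cell markers lowest for SSR (-0.71) and UVB (-0.62).

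Compared directly, UVB gave higher melanocyte genes and lower Langerhans and dendritic cell genes than UVA, though these lists had an adjusted p = 0.577 and 0.56 with an estimated correlation. The melanocyte mean was 0.73 ± 0.231 log2 higher after UVB (SD, n = 6, 6 of 6 volunteers), with 14 of 21 genes higher and 0 lower, PMEL by 1.47 log2 and TYRP1 by 1.41. The Langerhans and dendritic cell mean was -0.55 ± 0.301 (6 of 6 volunteers below 0), with 9 of 16 lower, CD1C by -1.03 and HLA-DRA by -0.88. The cell cycle mean was -0.26 ± 0.261, with 5 of 35 lower, including CCNB1, a cyclin of mitosis, and that of NRF2 targets -0.22 ± 0.249, with 3 of 23 lower. The largest single differences upward were SMIM43 (6.28-fold, 5 of 6 UVB and 1 of 6 UVA arrays well above background), GFRA4 (5.25-fold), WFDC8 (4.48-fold, 3 of 6 UVA arrays), SHANK2 (4.03-fold, 1 of 6 UVA arrays) and OR5AK2 (at least 1.93-fold, 5 of 6 UVB and 0 of 6 UVA arrays). The largest downward were SLIT2 (4.46-fold, 1 of 6 UVB arrays well above background), SYNE1 (3.83-fold, with another probe at -0.18 log2), TNFSF15 (2.83-fold, with its other probe at -0.09 log2, 4 of 6 UVB and 5 of 6 UVA arrays), SPP1 (2.81-fold, 4 of 6 UVB arrays) and ZRANB3 (at least 1.18-fold, 0 of 6 UVB and 5 of 6 UVA arrays).

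The paired comparison called 2459 genes higher and 918 lower after UVB than after UVA, 72.8% higher against 60.2% of 3626 calls under quantile normalization and 47.1% of 68 with normexp. A swap of the labels of 1 of the 6 volunteers called 3499 genes, more than the 3377 of the real labels, so chance is not excluded. In the unpaired comparison limma called 0, with 2688 at an unadjusted p under 0.05. The melanocyte list had an adjusted p of 8.51e-07 paired and 0.00307 unpaired, and the Langerhans and dendritic cell list 9.6e-09 and 2.16e-05. The cell cycle and NRF2 lists, with adjusted p of 1.51e-05 and 0.00385, each had an adjusted p = 0.577 with an estimated correlation. With slide as a fixed block 0 genes were called, and GFRA4, SMIM43 and SYNE1 turned direction. The melanocyte and Langerhans and dendritic cell means were then 1.04 and -0.68 when paired. Unpaired, within the slide that holds 2 UVA and 2 UVB arrays, they were 2.46 and -0.27. The unpaired values were not matched by volunteer and also hold differences between persons. Without the dim slide 79 genes were called, with means of 0.83 and -0.50, while with that slide kept, leaving out 1 volunteer at a time gave from 1417 to 4196.

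SSR also gave higher melanocyte genes and lower Langerhans and dendritic cell genes than UVA, though both lists had an adjusted p = 0.096 with an estimated correlation. The melanocyte mean was 0.92 ± 0.46 log2 higher (SD, n = 6, 6 of 6 volunteers), with 12 of 21 genes higher, TYRP1 by 1.98 and PMEL by 1.54, and the Langerhans and dendritic cell mean was -0.63 ± 0.324 (6 of 6 volunteers below 0), with 8 of 16 lower. Cell cycle genes had a mean of -0.35 ± 0.093 (6 of 35 lower, including UBE2C and CCNB1) and metallothioneins -0.34 ± 0.188 (4 of 10 lower, including MT1M and MT1X), each below 0 in 6 of 6 volunteers. CCL18 was 4.46-fold higher after SSR, PCSK2, a prohormone convertase, 3.81-fold (both with 5 of 6 UVA arrays well above background), ABCA13 6.40-fold (2 of 6 UVA arrays) and OR5AK2 at least 1.49-fold (5 of 6 SSR and 0 of 6 UVA arrays). GCNT3, SLIT2, MFAP5, ZG16 and TFPI2 were 6.14-fold, 4.82-fold, 3.87-fold, 3.82-fold and 3.76-fold lower, with 3, 5, 4, 4 and 4 of 6 SSR arrays well above background, and TFPI2 on 5 of 6 UVA arrays.

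The paired comparison called 412 genes higher and 631 lower after SSR than after UVA, and the unpaired one 0 higher and 4 lower, of which only FAM43B (2.32-fold lower) has a current symbol. The second probe of FAM43B changed by 0.62. The melanocyte and the Langerhans and dendritic cell lists had adjusted p of 4.4e-16 and 1.06e-13 when paired and 3.53e-09 and 2.2e-09 when unpaired. The cell cycle and metallothionein lists had adjusted p of 4.46e-10 and 3.18e-07, and 0.227 each with an estimated correlation. At the preset correlation alone, the ceramide barrier (mean 0.37), cholesterol synthesis (0.27) and p53 targets (0.22) were called higher and the inflammatory (-0.23), T and NK cell (-0.31) and NRF2 (-0.12) lists lower, with adjusted p = 0.156 or more with an estimated correlation. No SSR array shares a slide with a UVA array, and leaving out 1 volunteer at a time gave from 392 to 862 paired calls. With normexp, where the median of all genes was -0.333, the metallothionein mean was -0.19 (adjusted p of 0.761). ABCA13 and OR5AK2 turned to negative differences there, but ABCA13 stayed above that median.

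Between SSR and UVB 0 melanocyte and 0 Langerhans and dendritic cell genes were called. The melanocyte mean was 0.19 ± 0.263 log2 higher after SSR (SD, n = 6, 5 of 6 volunteers, adjusted p of 0.0534), with 0 of 21 genes called, and the Langerhans and dendritic cell mean was -0.09 ± 0.228 (adjusted p of 0.858), with 0 of 16 called. Metallothioneins were lower after SSR, with a mean of -0.40 ± 0.267 in 6 of 6 volunteers and 7 of 10 genes called, MT1A by -0.53 and MT1X by -0.48. Cholesterol synthesis genes had a mean of 0.24 ± 0.427, with 3 of 19 higher. ABCA13, LRRTM1, NLRP12 and ZNF420 had the largest positive differences, from 1.15 log2 for ZNF420 to 1.89 for ABCA13, with ABCA13, NLRP12 and ZNF420 well above background on 3 of 6 UVB arrays and the other probe of NLRP12 at 0.41. ZRANB3, on 5 of 6 SSR and 0 of 6 UVB arrays, was called higher with no fold to be given. GFRA4, PRR35, GCNT3, ZG16 and FOXR1 were 7.10-fold, 4.88-fold, 4.57-fold, 4.43-fold and 4.16-fold lower after SSR, with 3 and 4 of 6 SSR arrays well above background for GCNT3 and ZG16, and 5 of 6 UVB arrays for GCNT3.

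The paired comparison called 337 genes higher and 1287 lower after SSR than after UVB, 20.8% higher against 34.1% of 1847 calls under quantile normalization. In the unpaired comparison limma called 0, with 1823 at an unadjusted p under 0.05. The metallothionein and cholesterol lists had adjusted p of 2.11e-06 and 0.00252 when paired and 9.59e-07 and 0.0022 when unpaired, with adjusted p = 0.961 each with an estimated correlation when paired. Without the dim slide 6 genes were called, with a metallothionein mean of -0.63, while with that slide kept, leaving out 1 volunteer at a time gave from 58 to 1574. Without the dim slide the melanocyte mean was 0.09 (adjusted p of 0.148) when paired and -0.64 (adjusted p of 0.0231) when unpaired. The unpaired value sets all SSR arrays against the 2 UVB arrays left, not matched by volunteer. With normexp the melanocyte mean was -0.06 (adjusted p of 0.0296 paired and 0.0392 unpaired), where the median of all genes was -0.334. With normexp the metallothionein mean was -0.28 (adjusted p of 0.199). ABCA13, NLRP12, ZNF420 and ZRANB3 turned to negative differences there, but ABCA13 stayed above that median of all genes. No SSR array shares a slide with a UVB array.

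The genes called against control overlapped. After both SSR and UVB 356 genes rose and 277 fell in the paired comparison, after UVA and UVB 402 rose and 52 fell, and after SSR and UVA 34 rose and 7 fell, with 0 called in opposite directions in each pair. Independent lists of the same lengths would share 82.9 risen and 27.6 fallen genes, 119 and 5.69, and 8.91 and 0.918. Because the comparisons share their control arrays, the fold changes of all genes are correlated without any effect: across genes, which are not independent replicates, r was 0.694 for SSR and UVB, 0.537 for UVA and UVB and 0.458 for SSR and UVA, against medians of 0.554, 0.552 and 0.572 in 50 simulated draws of unchanged groups with shared controls. The simulated r ran from -0.114 to 0.824, -0.193 to 0.84 and -0.0713 to 0.837, so all 3 observed values lie within that range. The covariance was 0.103, 0.0775 and 0.0442 against simulated 0.0234, 0.0214 and 0.0217, a difference of 0.08, 0.0561 and 0.0225. Simulated covariances reached 0.0613, 0.0767 and 0.0777, so the value for SSR and UVA lies within their range. With each comparison taken from another 3 of the 6 volunteers, so that no control array was shared, r was 0.453, 0.355 and 0.22 and the covariance 0.0848, 0.0597 and 0.0272 (medians of 20 choices). Slides were not separated by this: all control arrays lie on slides 1 and 2, and UVA and UVB on neither. A difference between slides could therefore also give a positive r.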

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

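Melanocyte genes rose and Langerhans and dendritic cell genes fell after both SSR and UVB, which is the pattern weighed first, followed by the excess of rises after UVA and after UVB. The tests of scaling and all tests of the melanocyte and Langerhans lists, those of slides included, were chosen only after the result was seen. For these lists an earlier test of slides was replaced by 2 others whose values were already known when their rules were written. The other tests of slides were set before.

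The melanocyte list had a mean change of 1.42 log2 after SSR and 1.23 after UVB, above 0 in 6 of 6 volunteers each, and the Langerhans and dendritic cell list one of -0.71 and -0.62, with an adjusted p = 0.0135 for both after SSR and 0.472 for both after UVB with an estimated correlation. A lower share of keratinocyte RNA in the irradiated biopsies would raise the markers of every other cell type. The Langerhans mean was -0.623 ± 0.267 after UVB, the weaker of the 2 falls. That fall is itself part of the pattern being weighed, so it is no separate test. No conclusion on the share of keratinocyte RNA is drawn from it. For SSR, means of 1.28 and -0.99 with slide as a fixed block and volunteers paired argue against slides as the whole cause. However, only 1 slide holds both SSR and control arrays, 2 of each. These are not matched by volunteer, so differences between persons are set level only by the volunteer block. No UVB array shares a slide with control, so for UVB an effect of slides cannot be told apart, although with slide fixed the melanocyte mean was 1.04 higher after UVB than after UVA. More melanocytes, more transcript per melanocyte and a loss of Langerhans cells or of their transcripts may each play a part, and arrays of whole biopsies cannot separate these.

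After UVA 568 of 637 called genes rose, among them BMP3, MFAP5 and KRT14. If scaling by the 75th percentile made this excess, quantile normalization would bring the share that rose near even. It was 83.2% of 184 calls, which argues against scaling as the whole cause of the uneven share. The calls themselves fell from 637 to 184 there, and 25 of the 35 named genes called lost their call, KRT14 among them. How much of the excess depends on scaling therefore stays open. UVA and control lie on different slides, and the genes risen after UVA were measured after SSR in volunteers not used to choose them. There the median change after SSR was 0.336 of that after UVA, from -0.035 to 0.791 over 20 choices of volunteers. In log2 the genes so chosen, a new set in each choice, changed by a median of 0.404 after UVA, 0.144 after SSR and 0.405 after UVB. UVB shares no slide with control either. An effect of slides and one of UVA therefore cannot be told apart. The range is too wide to decide, and the effect of UVA stays open.

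After UVB 5280 of 7357 called genes rose, among them GFRA4, ASIP and SPARC. The share was 55.9% under quantile normalization, but that setting centres every array and so pulls it to even by itself, and it was 65.7% under median scaling, so an effect of scaling cannot be told apart from the others. For genes chosen in the 4 volunteers on the dim slide, the median rise was 0.58 in those 4 and 0.726 in the other 2. That is a ratio of 1.25, where other pairs of volunteers gave from 0.523 to 1.2, which argues against the dim slide alone as the cause. The other 2 UVB arrays lie on slide 5, which holds no control either. Its mean 75th percentile was nearly as low, at 982 against 937, so a cause common to both slides is not tested. The median change after SSR was 0.405 of that after UVB (0.17 to 0.644). In log2 the genes so chosen changed by a median of 0.554 after UVB, 0.21 after SSR and 0.173 after UVA. An effect of the slide set and one of UVB therefore cannot be told apart. UVB itself stays open as the biological explanation.

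In 16 of 190 groups of 6 arrays or 6 volunteers, 1 value lay farther from its nearest neighbour than a threshold that chance passes in about 1 group of 20. The values that follow are that gap as a share of the group's whole range. For gene lists after UVB it was 0.782 for stress keratins and epidermal alarmins, 0.743 for the ceramide barrier, 0.686 for cholesterol synthesis, 0.685 for basal keratinocytes and 0.66 for matrix proteases and their inhibitors. For lists after UVA it was 0.728 for haemoglobin markers, 0.644 for muscle markers and 0.638 for dermal extracellular matrix, and after SSR it was 0.655 for Langerhans and dendritic cell markers. Among single genes it was 0.773 for LORICRIN, 0.672 for COL1A1 and 0.629 for KITLG after UVB, and 0.701 for LORICRIN and 0.65 for HMOX1 after UVA. Among the measures of array quality it was 0.706 for spots marked as outliers on control arrays and 0.667 for saturated spots on UVB arrays.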

How the results depend on the processing

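The rise of melanocyte genes and the fall of Langerhans and dendritic cell genes after SSR and UVB kept their direction in every alternative run. In the paired comparison the melanocyte mean ran from 1.12 to 1.55 log2 after SSR, from 1.13 to 1.34 after UVB and from 0.43 to 0.57 after UVA, and the Langerhans mean from -0.99 to -0.56 and from -0.70 to -0.46 after SSR and UVB. The alternatives for the paired comparison, the fixed slide block there, the fits without the dim slide and the overlap from separate volunteers were chosen after seeing the data.

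For the gene lists, 2565 of 2755 reruns of the unpaired comparison kept direction and side of the threshold, 102 lost a call, 81 gained one and 7 turned direction. The paired numbers were 1331 of 1450, 33, 81 and 5. For the named genes they were 11521 of 12447, 285, 637 and 4 unpaired, and 5503 of 6312, 727, 54 and 28 paired. The cause was not tested for the changes below except where a sentence gives one.

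Pairing the volunteers gave 730 called genes for SSR, 637 for UVA and 7357 for UVB against control, 3377 for UVB against UVA, 1043 for SSR against UVA and 1624 for SSR against UVB. The genes shared were 41 for SSR and UVA, 633 for SSR and UVB and 454 for UVA and UVB. With quantile normalization as well, the counts were 704, 184, 7002, 3626, 1069 and 1847. With each comparison in another 3 volunteers, SSR and UVB shared a median of 60 genes over 20 choices, with fewer volunteers in each fit.

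For the unpaired comparison, quantile normalization called 1 gene for SSR, 98 for UVB, 16 for UVB against UVA and 2 for SSR against UVA, and median scaling 75 for UVB. Normexp background correction called 0 for UVB and for SSR against UVA. Without a mean-variance trend there were 1 for SSR, 397 for UVB, 115 for UVB against UVA and 0 for SSR against UVA. Fitting only the arrays compared gave 1 for SSR, 1 for UVB and 0 for SSR against UVA. Slide as a random block gave 5 for SSR, 1932 for UVB and 641 for UVB against UVA. Without a filter on dim probes, where more probes are tested, there were 1 for SSR, 4236 for UVB, 74 for UVB against UVA, 0 for SSR against UVA and 2397 for SSR against UVB. Array weights gave 67 for SSR and 1617 for UVB, and the mean of all probes 2 for SSR and 0 for SSR against UVA. Without the 4 arrays of the dim slide 0 were called for UVB, with fewer arrays compared. Leaving out 1 array or volunteer gave from 0 to 4 for SSR, 3 to 1478 for UVB, 0 to 592 for UVB against UVA, 0 to 3 for SSR against UVA and 0 to 2 for SSR against UVB.

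In the paired comparison, normexp called 204 genes for SSR, 239 for UVA, 1981 for UVB, 68 for UVB against UVA, 356 for SSR against UVA and 175 for SSR against UVB. For UVA there were 184 with quantile normalization, 348 without a trend, 228 with slide as a random block and 312 at 1.5-fold or more. The random block also gave 569 for SSR against UVA and 657 for SSR against UVB. The 1.5-fold minimum gave 4042 for UVB, 2244 for UVB against UVA, 690 for SSR against UVA and 969 for SSR against UVB. Without the filter there were 11138 for UVB, 5103 for UVB against UVA and 5323 for SSR against UVB, and with array weights 2464 for SSR and 1578 for UVA. Slide as a fixed block, which leaves the comparison mostly to 2 arrays against 2, gave 0 for SSR and 0 for UVB against UVA. Without the dim slide there were 4194 for UVB, 79 for UVB against UVA and 6 for SSR against UVB. Leaving out 1 volunteer gave from 382 to 580 for SSR, 17 to 538 for UVA, 4768 to 6493 for UVB, 1417 to 4196 for UVB against UVA, 392 to 862 for SSR against UVA and 58 to 1574 for SSR against UVB.

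Among lists, the melanocyte call after UVA was lost in the unpaired comparison with normexp (mean 0.476) and array weights (0.33), and its mean ran from 0.221 to 0.859 with 1 array or volunteer left out. With an estimated correlation the unpaired melanocyte calls were lost for SSR (1.418), UVA (0.504) and UVB (1.228), and the paired ones for UVA (0.503) and UVB (1.228). With slide fixed, the unpaired SSR means turned to 0.249 for cell cycle, 0.688 for matrix proteases, 0.064 for NRF2 targets and 0.194 for the inflammatory list. These unpaired values also hold differences between persons. The paired SSR means turned to 0.545 for late differentiation, 0.23 for NRF2 targets and 0.401 for the ceramide barrier. With normexp the neutrophil mean after UVA turned to 0.551 and the inflammatory mean after UVB to 0.16, paired or not. The medians of all genes were 0.376 and 0.385 there, so the inflammatory mean stayed below its median. Without the dim slide the circadian mean after UVB turned to -0.203.

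Normexp moved the median of all genes to 0.083 for SSR, 0.376 for UVA, 0.385 for UVB, 0.052 for UVB against UVA, -0.333 for SSR against UVA and -0.334 for SSR against UVB. With it, the fitted values after UVB, which for ZRANB3, SUPT3H, MCMDC2, SLN and FCGR3B set UVB arrays at background against control and give no fold, turned to 0.723 for ZRANB3, 0.892 for SUPT3H, 0.936 for MCMDC2 and 0.777 for SLN, paired or not, and in the paired comparison to 0.264 for CD8A, 0.79 for FCGR3B, 0.732 for NTM, 0.376 for SLIT2, 0.491 for GPR85, 0.554 for SLC7A11, 0.55 for CD247 and 0.044 for HPGDS. After UVA they turned to 0.556 for WNT5A, 0.158 for FBXO36, 0.398 for ABCC4 and 0.04 for SLC40A1. For SSR against UVA they turned to -0.009 for ABCA13 and -0.666 for OR5AK2, and for SSR against UVB to -0.9 for MCMDC2, -0.041 for ABCA13, -0.919 for NLRP12, -0.605 for ZNF420 and -0.92 for ZRANB3, where MCMDC2 and ZRANB3 are again at background after UVB. Quantile normalization turned KRT10 to -0.093 after UVB, and the mean of all probes turned MMP1 to 0.694. With slide fixed, the differences of UVB from UVA turned to -0.239 for SMIM43, -0.102 for GFRA4 and 0.304 for SYNE1.

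The signal over background limits what can be said of dim genes. MCMDC2, SUPT3H, ZRANB3, SLN and FCGR3B, called lower after UVB, were well above background on 0 of 6 UVB arrays, and the 4 UVB arrays of the dim slide had the lowest shares of probes well above background.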

Other observations

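Genes that keratinocytes and fibroblasts use to signal to melanocytes moved both ways. Of 22 paracrine pigmentation factors, 5 rose and 5 fell after UVB (mean -0.04), 0 rose and 3 fell after SSR (-0.09), and 0 were called after UVA (-0.08). Of all 25173 genes 5280 rose and 2077 fell after UVB, and 395 rose and 335 fell after SSR. The tests of splits in this part were set before the data were examined, and the overlap from separate volunteers was chosen after seeing them.

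Lists that mark structures of the dermis and the fat below it had positive means after UVB without passing in the list test. They were adipocytes (0.49, 4 of 9 rose), Schwann cells and nerve (0.40, 4 rose and 1 fell of 9), mast cells (0.35, 4 rose and 1 fell of 8), endothelium (0.28, 3 of 8 rose), macrophages (0.27, 5 rose and 2 fell of 15), sebaceous gland and hair follicle (0.26, 4 of 11 rose), muscle (0.24, 1 of 9 rose) and sweat gland (0.18, 3 of 9 rose). These counts stand beside 5280 risen and 2077 fallen of all 25173 genes. The macrophage genes FOLR2 and C1QB were 4.19-fold and 1.74-fold higher after UVB, and FOLR2 2.96-fold after UVA, while its other probe changed by 0.70 log2 after UVB and 0.02 after UVA. The mast cell factor GATA2 was 2.33-fold higher after UVB and called in the unpaired comparison too. LPL, of adipocytes, was 2.69-fold, 1.71-fold and 2.10-fold higher after SSR, UVA and UVB, with 5 of 6 control arrays well above background.

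After SSR the means of these 8 lists, in the same order, were 0.35, 0.43, 0.18, 0.26, -0.04, 0.23, 0.16 and 0.14, and after UVA 0.13, 0.09, 0.18, -0.16, -0.00, 0.09, 0.05 and -0.09. Haemoglobin markers changed by -0.25 after SSR, -0.45 after UVA and -0.16 after UVB. The biopsies hold epidermis and dermis in shares that were not measured here, so these means were not read as changes within cells. Of the markers listed, 9 of 12 for adipocytes, 8 of 12 for endothelium and 8 of 11 for mast cells were tested. LEP, PLIN1, FABP4, TEK, TIE1, EMCN, TPSAB1, CMA1 and the matrix gene LUM were among those not tested. In control skin the scaled log2 signal was -6.74 for COL3A1, -5.47 for FBN1, -2.27 for COL1A1 and 1.5 for SPARC, against 3.9 for CD1A. The biopsies may therefore hold little dermis or fat, and the list means may rest on few cells.

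For 5 further lists no call was made in the list test, while single members passed. The means after SSR, UVA and UVB were -0.01, 0.03 and 0.03 for nucleotide excision repair, -0.02, -0.00 and 0.09 for the interferon response, -0.06, 0.06 and 0.00 for matrix proteases and their inhibitors, -0.06, -0.14 and 0.06 for stress keratins and epidermal alarmins, and 0.01, -0.09 and 0.02 for the circadian clock. After UVB 3 members rose and 1 fell of 24 repair genes, 26 stress keratins and alarmins and 17 clock genes each, 3 rose and 3 fell of 20 proteases and inhibitors, and 2 rose of 22 interferon genes. With 5280 risen and 2077 fallen of all 25173 genes, such single calls mark no response of these lists. Among them ERCC2 and LIG1, of repair, were 1.58-fold and 1.25-fold higher, LCE3C and KRT16 1.93-fold and 1.35-fold and TIMP2 1.71-fold. For vitamin D metabolism they were 0.19, -0.03 and 0.23, with CYP24A1 higher after each exposure, by 1.51-fold, 1.48-fold and 1.88-fold. The smallest adjusted p of these 16 lists in the 3 comparisons was 0.0521, for haemoglobin after UVA. Where a mean lies this near 0 the list test, which sets a list against all other genes, need not follow its sign. After UVB it gave a downward direction for nucleotide excision repair, interferon, stress keratins, matrix proteases and circadian clock, and after UVA for muscle and Schwann cells, whose means are above 0.

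Swapping the labels within volunteers tests whether the paired counts rest on chance. Of 32 swaps, the real one included, only the real one gave as many genes for SSR (730, highest other 92), UVA (637, highest other 1), UVB (7357, highest other 924), SSR against UVA (1043, highest other 9) and SSR against UVB (1624, highest other 3). That is 1 in 32, the smallest share this test can give. The real labels also follow the slides, which a swap mixes, so an effect of slides could give the same result. For UVB against UVA 2 of 32 did, with 3377 for the real labels and 3499 for a swap that reverses 1 of the 6 volunteers, so chance is not excluded. That swap leaves all 4 arrays of slide 4 on the UVA side and 3 of the 4 on slide 6 on the UVB side, and with slide as a fixed block 0 genes were called.

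For the unpaired counts 100 splits of the 12 arrays into 6 and 6 were drawn, the real one included. For UVB (264 genes, highest other 1) and for SSR against UVA (4 genes, highest other 0) only the real split, 1 of 100, called as many. Such splits ignore that arrays of 1 volunteer vary together, and the real groups also follow the slides. They therefore cannot exclude chance or an effect of slides. For SSR, UVA, UVB against UVA and SSR against UVB the real split called 0, which all 100 of 100 splits reach by necessity, so these splits say nothing about chance. Other splits called up to 4477 genes for UVA and 5739 for UVB against UVA, which points to a structure of the samples. In the 32 swaps that keep each volunteer on both sides the highest unpaired count of another swap was 0, so the large counts came from splits that part volunteers unevenly.

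SSR and UVB, taken from separate volunteers in 20 choices of 3 and 3, shared a median of 38.5 risen and 13.5 fallen genes with 0 in opposite directions. For the other pairs of exposures the medians were 0 and 0.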
